A study of Mus musculus with 2 samples.

How the data were processed

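The samples were 2 single-cell libraries of CD45-positive cells sorted by flow cytometry from mouse retinas, prepared with a 10x 3' kit. The PBS and the Igfbpl1 group had 1 library each, pooled from 10 glaucomatous mice per group aged 8 to 10 months. Per the labels, mice were perfused with saline and retinas dissociated with enzymes for 1 hour before staining. The deposited values are UMI counts per gene and cell barcode, not normalised. Cell Ranger 3.1 and the mm10 genome build are named in the submitters' processing notes. The filter applied to cells before deposit is not given in the sources used here. The lowest totals per cell were 1003 UMIs and 529 genes in the PBS library and 1001 UMIs and 502 genes in the Igfbpl1 library, and the highest mitochondrial percentages 14.5% and 14.6%. The deposited counts list 15579 genes for the PBS library and 17273 for the Igfbpl1 library, of which 15169 were shared, 410 were only in the PBS library and 2104 only in the Igfbpl1 library. A gene listed for 1 library only was given a value in that library alone and no ratio.

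Counts were read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15 and handled with scanpy 1.11.5 and anndata 0.12.19. A cell filter of at least 200 genes and at most 20% mitochondrial UMIs removed 0 cells. Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was clustered by the Leiden method (scikit-learn 1.9.0 and igraph 0.11.9, resolution 0.8, seed 0) into 19 clusters. Clusters were named from 24 marker sets, by the share of a set's markers that were raised, with a minimum of 3 markers. Raised meant at least 2-fold over the median of the cluster means, with 20 CPM added. The marker also had to be detected in at least 10% of the cluster. The 10 top genes of each cluster, among genes detected in 25% of its cells and with 50 CPM added, were listed beside the name. Doublets were called with Scrublet within each library, 6 of 1055 cells (0.569%) and 62 of 3330 (1.86%), and kept in the values reported.

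Expression was compared on UMIs summed over the cells of a class, as CPM of the class total, in classes with at least 20 cells per library. Exact 95% intervals came from scipy 1.17.1: Poisson for CPM, conditional binomial for ratios and Clopper-Pearson for shares. A share of 0 has the upper limit that 3 counts allow. Log2 ratios had 10 CPM added to both libraries, and folds and their intervals had nothing added. Genes at a mean of 50 CPM or more and 20 or more UMIs were measured. Named in microglia-like cells were at most 12 genes per direction with the largest ratios of at least 2-fold and 50 UMIs, and in other classes 3 per direction. Mitochondrial, ribosomal protein and clone-named genes were left out of this choice. From each list at most 2 members of highest expression and 2 of largest ratio were named, and a fixed set of further genes was named in any case, among them Igfbpl1, Igf1r and P2ry12. Some genes that these rules name are not reported here. Saa3, Cd163, Cldn5 and other genes listed in 1 library only, and the genes given in neurons, were chosen after their values were seen. Gene positions come from the GENCODE M21 annotation of mm10.

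The 24 gene lists were homeostatic and disease-associated microglia, inflammatory cytokines and NF-kB targets, anti-inflammatory and repair, type I interferon response, MHC class I and class II, complement, lysosome and phagocytosis, cholesterol and lipid efflux, cholesterol synthesis, IGF1 and PI3K-AKT-FOXO signalling, immediate early genes, heat shock, cell cycle, oxidative phosphorylation, glycolysis and hypoxia, unfolded protein response, oxidative stress and iron, apoptosis and p53, T cell activation, naive T cells, cytosolic ribosome and mitochondrially encoded genes. Each median was placed among 10000 random lists of the same size drawn from 20 expression bins (seed 1), and its counting interval came from 500 redraws of the counts (seed 3). A list with fewer than 3 genes measured has no percentile. Shares of cells with a UMI were taken after thinning every cell to 1000 UMIs (seed 2), with B-like cells as the class that should lack the gene. Figures were drawn with matplotlib 3.10.9.

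The groups, the comparisons, the filters, the marker sets, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The naming score of the clusters, their top-gene rule, the split by Xist and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty), the limit of 2000 UMIs in the check of shallow barcodes, the weighting by heat shock UMIs, the matching on genomic span in 5 bins of each property, and the naming of clusters at resolution 1.5 were chosen afterwards. Alternatives covered clustering resolutions of 0.4 and 1.5, each library clustered on its own, mitochondrial limits of 10% and none, a minimum of 500 genes, doublets left out, thinning to 1000 and 500 UMIs, 1 and 50 CPM added, minimums of 10 and 100 CPM, median-ratio scaling, other totals, equal weight per cell, the largest cluster alone, and list members not shared with other lists.

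The size rule, the fold intervals and the list percentiles were tested on simulated data made from the microglia-like totals over 3306 genes, with 200 genes changed (50 per direction and size, seed 11). All genes set 3-fold higher or lower and all set 2.5-fold higher lay past the 2-fold rule (100%), as did 72% of those set 2.5-fold lower, and 0 of 3129 unchanged genes did. The interval held the true fold for 95.6% of genes. Counts were drawn as Poisson from a shared profile, without variation between cells or libraries. The simulation therefore checks the calculation and not how the rules behave on real libraries. A list of 15 raised genes had percentile 100 and a list of 15 unchanged genes 72.8. A minimum of 50 CPM corresponds to fewer UMIs in small classes, so their ratios are less precise.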

Results

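Single-cell RNA sequencing measured the transcripts of CD45-positive cells sorted from the retinas of B6 mice with microbead-induced glaucoma, a model in which beads injected into the eye raise its pressure. The PBS group and the Igfbpl1 group each had 1 library, pooled per the labels from 10 mice aged 8 to 10 months. The PBS library held 1055 cells and 3795008 UMIs (unique molecular identifiers, which count transcripts), with a median of 3433 UMIs and 1625 genes per cell. The Igfbpl1 library held 3330 cells and 9463631 UMIs, with medians of 2355.5 UMIs and 1114.5 genes per cell. Median percentages of mitochondrial UMIs were 1.27% and 1.34%, and of ribosomal protein UMIs 10.6% and 16.4%. With 1 library per group there are no replicates, so no difference was tested. Each interval is an exact 95% interval (Clopper-Pearson for shares, Poisson for expression) that covers counting error only, and the values compare these libraries rather than the treatments. Igfbpl1 (insulin-like growth factor binding protein-like 1; mm10 chromosome 4, 45809468 to 45826923, minus strand) was listed in neither library.

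The first comparison asks how the mix of sorted immune cells differed between the PBS and the Igfbpl1 library. Microglia-like cells, the resident macrophages of the retina, made up 72.1% of the PBS library (761 cells, 69.3 to 74.8%) and 47.1% of the Igfbpl1 library (1570 cells, 45.4 to 48.9%). Other immune cells together made up 18.8% (198 cells, 16.5 to 21.3%) and 46.1% (1534 cells, 44.4 to 47.8%). T-like cells, natural killer (NK)-like cells and monocyte/macrophage-like cells held larger shares of the Igfbpl1 library, and B-like cells a smaller one. The difference, Igfbpl1 minus PBS, was -25.0 percentage points for microglia-like cells (-28.2 to -21.7) and 27.3 points for the other immune cells (24.3 to 30.2).

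Monocyte/macrophage-like cells made up 7.39% of the PBS library (5.89 to 9.14%) and 12.9% of the Igfbpl1 library (11.8 to 14.1%). That share depends on processing: it was 1.23% and 6.28% at a clustering resolution of 1.5, and 6.73% and 23.1% after thinning to 1000 UMIs. With that thinning the share of Igfbpl1 cells named dendritic-like fell from 13.2% to 3.06%, so the naming of cells moved between these classes. T-like cells, which carry the T cell receptor genes, made up 3.03% (2.08 to 4.26%) and 9.04% (8.09 to 10.1%). NK-like cells, cytotoxic lymphocytes, numbered 3 of 1055 cells (0.284%, 0.0587 to 0.829%) and 210 of 3330 (6.31%, 5.50 to 7.19%). Plasmacytoid dendritic-like cells, the lineage known for type I interferon secretion, numbered 3 and 76 cells, or 0.284% and 2.28% (1.80 to 2.85%). B-like cells, which carry immunoglobulin genes, made up 7.68% (6.14 to 9.45%) and 2.37% (1.88 to 2.95%). Cluster 14, with high MHC class II transcripts, held 1 PBS cell (0.0948%) and 335 Igfbpl1 cells (10.1%, 9.06 to 11.1%). It had 7 of 11 dendritic cell markers raised and 5 of 11 monocyte markers. Its top genes held no dendritic cell marker and 1 monocyte marker, Plac8, so it is compared by number. Cluster 17, marked by Ccr7 and Fscn1 of migratory dendritic cells, held 0 of 1055 PBS cells, which allows a share of up to 0.284%, and 103 Igfbpl1 cells (3.09%, 2.53 to 3.74%). Cluster 18, marked by Il17a and the gamma-delta T cell genes Trdc and Trdv4, held 0 PBS cells, with the same limit of 0.284%, and 65 Igfbpl1 cells (1.95%, 1.51 to 2.48%). A cluster found almost wholly in 1 library can mark that library rather than a cell type.

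Non-immune cells made up 9.10% of the PBS library (7.43 to 10.9985%) and 6.79% of the Igfbpl1 library (5.96 to 7.69%). Rod photoreceptors accounted for 3.89% (41 cells, 2.80 to 5.24%) and 0.420% (14 cells, 0.230 to 0.704%). Bipolar cell-like neurons numbered 26 and 112, Muller glia-like cells 19 and 61, and amacrine-like neurons 10 and 39. These shares follow the CD45 sort as well as the tissue, and median depth differed between the libraries. Among cells of 2000 UMIs or more, other immune cells made up 18.1% (168 of 930) and 55.7% (1159 of 2082), a difference of 37.6 points. In the Igfbpl1 library median depth was 2053 UMIs in microglia-like and 2968.5 in other immune cells. In the PBS library these medians were 3525 and 3054. The limit therefore left out more of the Igfbpl1 microglia-like cells, and the size of the difference depends on it.

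**Figure D1:**
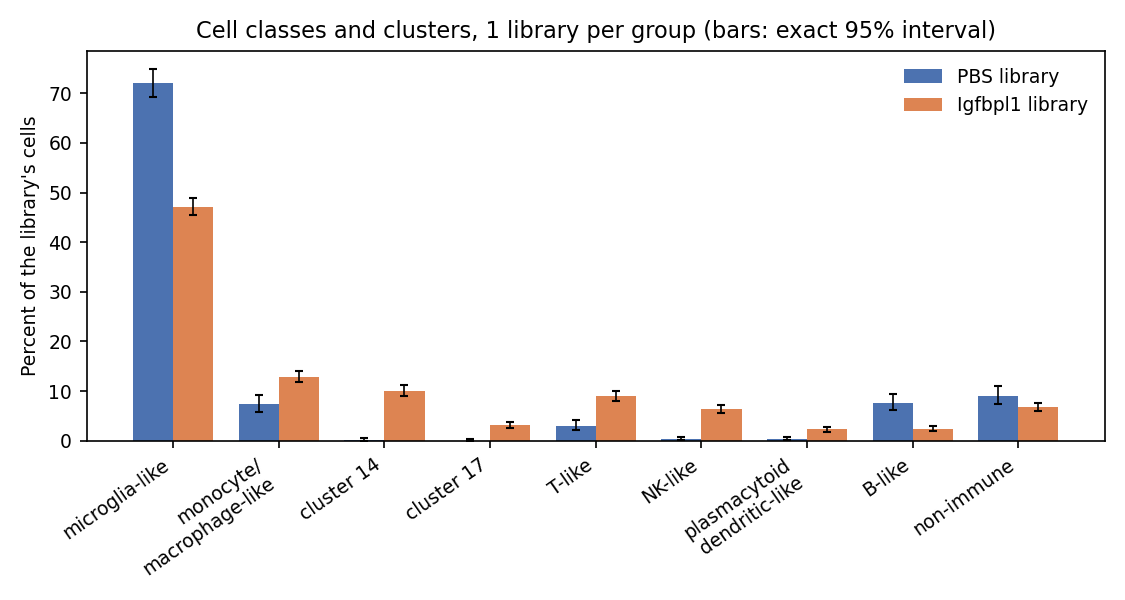
Percent of each library's cells (y axis) in each class or cluster (x axis), as bars with exact 95% Clopper-Pearson intervals, for the PBS and the Igfbpl1 library; clusters 14 and 17 are given by number. Microglia-like cells stand at 72.1% and 47.1%, and cluster 14 at 0.0948% and 10.1%.

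Sex-linked transcripts separated the cells of each pool, and the larger share of other immune cells was not shared by both sets of cells. A cell with UMIs of Xist, the RNA that coats the inactive X chromosome, and none of 4 Y-linked genes was called Xist-only, and the reverse Y-only. Among microglia-like cells assigned to either set, 65.8% were Y-only in the PBS library (61.7 to 69.8%) and 43.6% in the Igfbpl1 library (40.4 to 46.7%). Among the other immune cells, Y-only cells made up 66.7% (58.0 to 74.5%) in the PBS library and 5.84% (4.45 to 7.501%) in the Igfbpl1 library. T-like cells of the Igfbpl1 library were 3.83% Y-only (1.67 to 7.40%), NK-like cells 2.72% (0.746 to 6.82%) and monocyte/macrophage-like cells 8.52% (5.48 to 12.5%). Other immune cells made up 18.0% of Xist-only cells in the PBS library (45 of 250, 13.4 to 23.3%) and 59.4% in the Igfbpl1 library (919 of 1547, 56.9 to 61.9%). Among Y-only cells they made up 18.4% (90 of 490, 15.04 to 22.1%) and 10.2% (57 of 560, 7.80 to 12.99%). Microglia-like cells made up 75.2% and 35.9% of Xist-only cells but 73.9% (69.7 to 77.7%) and 76.6% (72.9 to 80.1%) of Y-only cells. Monocyte/macrophage-like cells made up 6.73% and 4.11% of Y-only cells, and T-like cells 3.06% and 1.43%. B-like cells made up 7.96% and 2.5% of Y-only cells and 4.8% and 1.55% of Xist-only cells, a smaller share in both sets. NK-like cells made up 0.204% and 0.714% of Y-only cells, and dendritic-like cells 0.204% and 1.25%. These NK-like and dendritic-like shares were larger in the Igfbpl1 library, but their intervals overlapped. The contrast between Xist-only and Y-only cells was not tested. The sex of the pooled mice is not given in the sources used here.

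**Figure D2:**
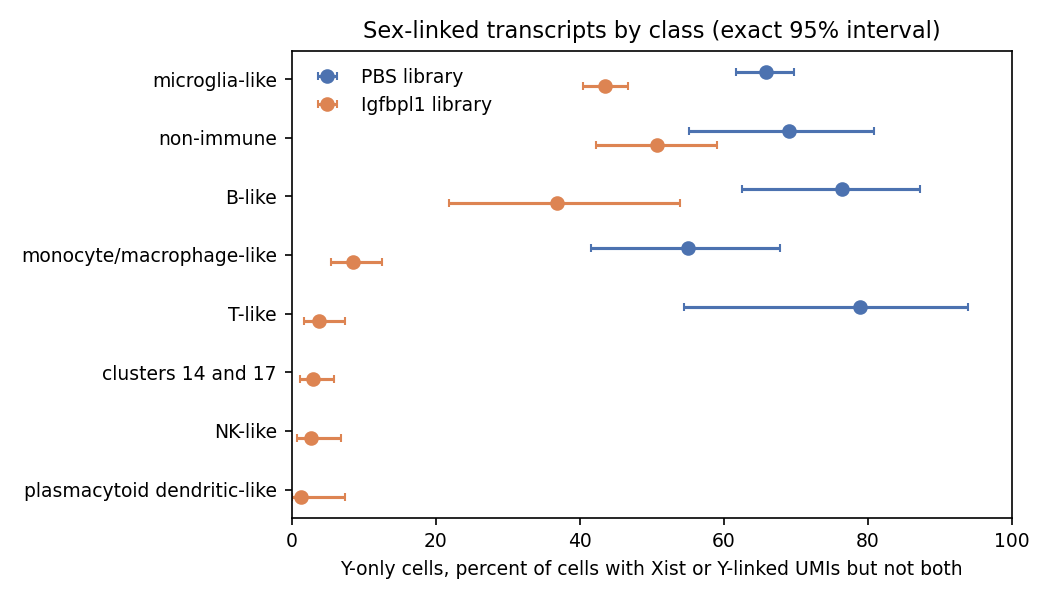
Percent of Y-only cells (x axis) among the Xist-only and Y-only cells of each class (y axis), as points with exact 95% Clopper-Pearson intervals, for classes with at least 10 such cells; clusters 14 and 17 are joined. Microglia-like cells stand at 65.8% in the PBS library and 43.6% in the Igfbpl1 library, and T-like cells at 78.9% and 3.83%.

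The second comparison asks how microglia-like cells of the Igfbpl1 library differed in expression from those of the PBS library. In the Igfbpl1 library 11 of 12 heat shock genes, 9 of 13 interferon response genes and 9 of 19 inflammatory genes were higher by at least 1.5-fold, and 8 of 20 homeostatic microglia genes lower. Il1b, the gene of the cytokine interleukin-1 beta, was 5.68-fold higher (5.003 to 6.46), at 98.9 CPM (the gene's UMIs scaled to a common class total) in the PBS library and 561 CPM in the Igfbpl1 library. Ccl2, a chemokine that attracts monocytes, was 4.15-fold higher (3.90 to 4.42), at 429 and 1783 CPM. P2ry12, the ADP receptor by which microglia are commonly recognised, stood at 0.519 times its PBS level (0.494 to 0.544), at 1489 and 773 CPM. These values come from 2799693 UMIs of the PBS library and 3638583 of the Igfbpl1 library, at median depths of 3525 and 2053 UMIs per cell. Most PBS cells of the class lay in cluster 2, and the largest numbers of Igfbpl1 cells in clusters 12 and 0.

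The gene with the largest ratio was Apoc1, an apolipoprotein gene beside Apoe (chromosome 7, 19689481 to 19692660, minus strand), at 6.07 CPM (3.54 to 9.72) and 105 CPM (94.5 to 116), a 17.2-fold ratio (10.6 to 29.9). That ratio was 45.4 among Xist-only cells (15.4 to 221, resting on 3 PBS UMIs) and 2.69 among Y-only cells (1.33 to 5.71). Hspb1, a small heat shock protein, stood at 96.8 and 574 CPM (5.93-fold, 5.22 to 6.76), and Dnajb1, a co-chaperone, at 321 and 1236 CPM (3.85-fold, 3.58 to 4.14). Wfdc17, expressed by activated macrophages, was at 44.3 and 239 CPM (5.40-fold, 4.47 to 6.58), and the kinase gene Pim1 at 22.5 and 104 CPM (4.62-fold, 3.53 to 6.13). Ifi27l2a, an interferon-induced gene, was at 263 and 1042 CPM (3.96-fold, 3.66 to 4.29). Hmox1, the haem-degrading enzyme, was at 281 and 994 CPM (3.54-fold, 3.27 to 3.82), and the fatty acid binding protein gene Fabp5 at 31.1 and 119 CPM (3.83-fold, 3.04 to 4.88). The MHC class II genes H2-Ab1, at 37.5 and 140.2 CPM (3.74-fold, 3.02 to 4.66), and Cd74, at 92.5 and 314 CPM (3.39-fold, 2.96 to 3.90), were higher as well. In bipolar-like and amacrine-like neurons, which are not known to express Cd74, it stood at 0 CPM in the PBS library (up to 22.7) and 259.9 CPM in the Igfbpl1 library (209.5 to 319), and H2-Ab1 at 0 and 155 CPM. The ratios among Xist-only and Y-only cells were 12.4 and 3.76 for Wfdc17, 9.94 and 2.72 for Ifi27l2a, and 43.2 (resting on 3 PBS UMIs) and 1.49 for Fabp5. Saa3, an acute-phase gene, was listed only in the Igfbpl1 library, where it stood at 80.0 CPM (71.1 to 89.7).

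**Figure D3:**
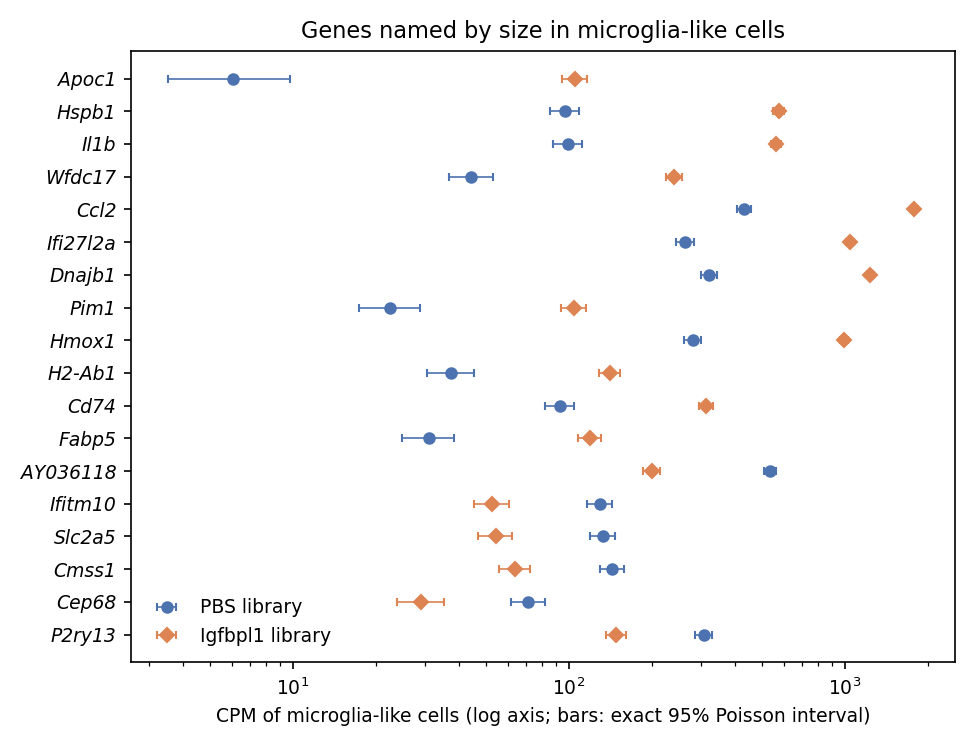
CPM of microglia-like cells (x axis, log scale) for the genes chosen by size of ratio (y axis), as points with exact 95% Poisson intervals, in the PBS and the Igfbpl1 library. Il1b stands at 98.9 and 561 CPM, and P2ry13 at 307 and 148 CPM.

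On the lower side the naming rule, which leaves out mitochondrial, ribosomal protein and clone-named genes, gave the purinergic receptor gene P2ry13 (307 and 148 CPM, 0.482-fold), the fructose transporter gene Slc2a5 (133 and 54.1 CPM, 0.409-fold), Ifitm10 (129 and 52.5 CPM, 0.407-fold), Cep68 (71.1 and 29.1 CPM, 0.410-fold), Cmss1 (144 and 63.5 CPM, 0.442-fold) and the non-coding RNA AY036118 (535 and 199 CPM, 0.373-fold). AY036118 and Cmss1 were lower in B-like cells too, at 1052 and 188 CPM and at 254 and 67.5 CPM. Tmem119, a microglial membrane protein gene (chromosome 5, 113793729 to 113800516, minus strand), stood at 738 and 396 CPM (0.537-fold, 0.502 to 0.575). The fractalkine receptor gene Cx3cr1 stood at 3119 and 2276 CPM, Csf1r, whose receptor microglia need to survive, at 1618 and 1135 CPM, and the lipid-sensing receptor gene Trem2 at 2392 and 2001 CPM.

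Apoe, a lipid carrier gene, stood at 4617 CPM in the PBS library and 9137 CPM in the Igfbpl1 library (1.98-fold, 1.94 to 2.02), but the ratio was 13.8 among Xist-only cells and 0.747 among Y-only cells. Its 12927 PBS UMIs lay in 402 of 761 cells, against 6697 Trem2 UMIs in 748 cells. They were thus clumped, which these intervals leave out. In the PBS library Apoe stood at 1132 CPM in Xist-only and 6638 CPM in Y-only cells. Osteopontin (Spp1) was at 49.3 and 101 CPM (2.06-fold, 1.69 to 2.52), but the ratio was 7.04 among Xist-only cells (4.02 to 13.5) and 3.61 among Y-only cells (2.47 to 5.39). Its 138 PBS UMIs lay in 16 of 761 cells, a clumping that these intervals leave out. The Xist-only and Y-only cells held 13 and 38 of those UMIs, and the rest lay in cells outside both sets. Tumour necrosis factor (Tnf) was at 234 and 203 CPM (0.867-fold, 0.779 to 0.965), with ratios of 1.19 among Xist-only and 0.662 among Y-only cells. For Il6 (15.7 and 11.3 CPM; 0.457 to 1.12) and Itgax (15.7 and 22.8 CPM; 0.995 to 2.14) a difference was not detectable at this depth. Igf1r, the receptor of insulin-like growth factor 1, was at 78.9 and 65.7 CPM, with a ratio of 0.832 whose interval reached 1.00 (0.684 among Xist-only and 1.16 among Y-only cells), and Igf1 itself at 3.93 and 8.52 CPM (1.06 to 4.78). Ptprc, which encodes CD45, stood at 588 and 720.1 CPM, and Cd68 at 470.1 and 386 CPM. Within the Xist-only cells (188 PBS and 556 Igfbpl1 cells) and the Y-only cells (362 and 429), the ratios were 6.85 and 4.57 for Il1b, 11.2 and 2.87 for Ccl2, 0.359 and 0.613 for P2ry12, and 0.492 and 0.559 for Tmem119.

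Gene lists fixed beforehand are given as median log2 ratios, Igfbpl1 over PBS with 10 CPM added, beside their percentile among 10000 random lists of like expression, which describes these libraries only, and a member counts as higher or lower at 1.5-fold on that scale. The median of all 3353 genes measured was -0.12. Scaling by the median ratio, which is -0.13 on the log2 scale, raises the log2 ratios of genes by at most that size. Of 20 homeostatic microglia genes, 8 were lower by at least 1.5-fold and 0 higher, with a median of -0.50 (-0.54 to -0.47, percentile 0). It was -0.73 among Xist-only and -0.43 among Y-only cells. Cst3, the gene of cystatin C, stood at 35262 and 28809 CPM (0.817-fold). Genomic span went with the ratio across genes (Spearman correlation -0.35, genes not being independent replicates), longer genes being lower in the Igfbpl1 library.

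Of 13 type I interferon response genes, 9 were higher by at least 1.5-fold and 0 lower, with a median of 0.92 (0.79 to 1.03, percentile 100). Ifi207, an interferon-induced gene, stood at 50.4 and 167 CPM (3.31-fold), and Bst2, which tethers viruses to the cell, was 1.43-fold higher. The list's median was 1.57 among Xist-only but 0.20 among Y-only cells. Of 19 inflammatory cytokine and NF-kB target genes, 9 were higher and 0 lower (median 0.47, 0.38 to 0.58, percentile 100; 1.08 among Xist-only and 0.35 among Y-only cells). The chemokine genes Ccl4, at 4382 and 8935 CPM (2.04-fold), and Ccl3, at 2248 and 3594 CPM (1.60-fold), were its most abundant members. MHC class II genes had a median of 0.85 (0.72 to 0.93, percentile 100), with 2 of 4 higher, while H2-DMa, which loads peptides, had a ratio of 1.04. The median was 1.66 with a minimum of 10 CPM in place of 50. Of 10 MHC class I genes, 1 was higher, H2-Q7 (2.28-fold), while Tapbp had a ratio of 0.645 and B2m, the shared light chain, 1.30 (median 0.27, percentile 99.1, or 93.9 among lists also matched on genomic span, inside the middle 95%). That median was 0.80 among Xist-only and -0.016 among Y-only cells.

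Heat shock genes, chaperones that warming and cell isolation are known to induce, had a median of 1.11 (1.05 to 1.16, percentile 100), with 11 of 12 higher. Hspa1a stood at 3908 and 5963 CPM (1.53-fold) and Hspa1b, its near-identical copy whose reads can be split between both genes, at 1.05-fold. Median heat shock UMIs per 1000 UMIs of a cell were 10 and 22. Of 21 immediate early genes, the rapid transcription factors of stimulated cells, 8 were higher and 0 lower (median 0.50, 0.44 to 0.56, percentile 100). Fos stood at 1787 and 3645 CPM (2.04-fold), Atf3 at 1089 and 3153 CPM (2.90-fold), Nr4a1 at 2.37-fold and Jun at 1.16-fold. The heat shock median was 1.23 among Xist-only and 1.02 among Y-only cells, and the immediate early median 0.98 and 0.34.

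Of 16 disease-associated microglia genes, 7 were higher and 2 lower (median 0.31, 0.26 to 0.37, percentile 99.3; 0.70 among Xist-only and 0.17 among Y-only cells). The growth factor gene Csf1 was 2.44-fold higher, while the protease gene Ctsd had a ratio of 0.999. Of 9 cholesterol and lipid efflux genes, 4 were higher (median 0.35, percentile 99.965; 0.89 among Xist-only and 0.20 among Y-only cells), with the sterol carrier Npc2 at 1.28-fold. Of 10 oxidative stress and iron genes, 3 were higher (median 0.27, percentile 99.2, or 96.9 with span matched, inside the middle 95%; 0.44 among Xist-only and 0.18 among Y-only cells), the ferritin genes Fth1 (4617 and 8035 CPM, 1.74-fold) and Ftl1 (1.61-fold) among them. Of 29 nuclear oxidative phosphorylation genes, 0 reached 1.5-fold on this scale and 26 had a log2 ratio above 0 (median 0.26, percentile 100). Among them the cytochrome oxidase subunit genes Cox8a and Cox5a were 1.49-fold and 1.52-fold higher and the ATP synthase subunit gene Atp5e 1.43-fold higher.

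**Figure D4:**
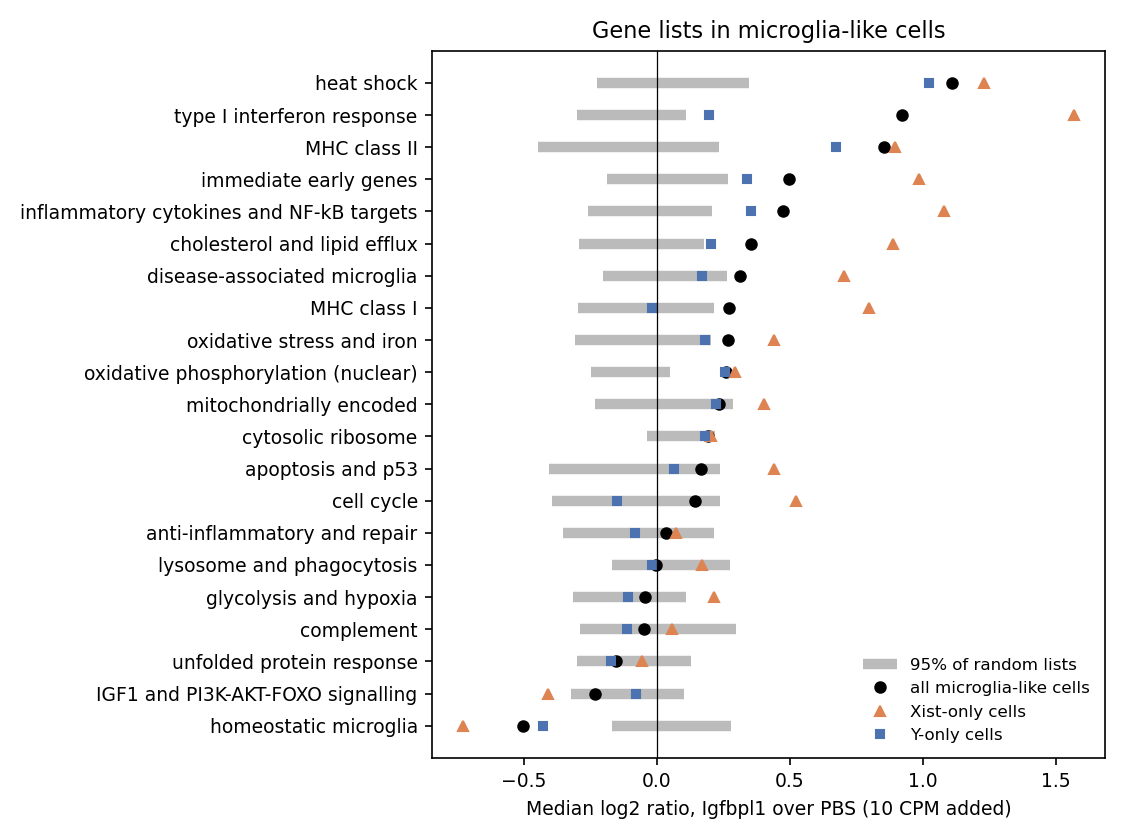
Median log2 ratio, Igfbpl1 over PBS with 10 CPM added (x axis), of each gene list in microglia-like cells (y axis), for all, Xist-only and Y-only cells; grey bars span 95% of random lists of like expression. The heat shock list stands at 1.11 and the homeostatic list at -0.50, with Y-only values of 1.02 and -0.43.

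The remaining lists with a percentile lay within the middle 95% of random lists. Complement genes had a median of -0.049 (percentile 43.3), with C1qa at 1.05-fold, C1qb at 1.07-fold and the receptor gene C5ar1 at 0.775-fold. Lysosome and phagocytosis genes had a median of -0.0035 (percentile 34.3), with the protease gene Ctss at 1.10-fold and the phagocytic receptor gene Axl at 1.72-fold. Anti-inflammatory and repair genes had a median of 0.036 (percentile 81.5), with Socs3, a brake on cytokine signalling, at 236 and 654 CPM (2.78-fold), Tgfbr2 at 0.761-fold and the glucocorticoid receptor gene Nr3c1 at 0.709-fold. Of 11 genes of IGF1 and PI3K-AKT-FOXO signalling, 1 was lower, Pik3cg (0.567-fold), and the median was -0.23 (percentile 14.1; -0.41 among Xist-only and -0.077 among Y-only cells), with Pik3r1 at 0.868-fold, Gsk3b at 0.872-fold and Irs2 at 1.59-fold. Glycolysis and hypoxia genes had a median of -0.043 (percentile 76.1), with Hif1a at 1.59-fold and Gapdh at 0.744-fold. The medians for complement, lysosome and glycolysis genes turn above 0 under median-ratio scaling, so no direction is given for them.

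Unfolded protein response genes had a median of -0.15 (percentile 35.6), with the chaperone genes Hspa5 at 1.35-fold, Hsp90b1 at 0.912-fold and Dnajb9 at 0.716-fold. Cytosolic ribosome genes had a median of 0.19 (percentile 93.5), with Rpl39 at 1.25-fold, Rps29 at 0.844-fold and Rpl22l1 at 1.67-fold. Mitochondrially encoded genes had a median of 0.23 (percentile 92.4), with mt-Co1 at 1.38-fold and mt-Nd3 at 0.716-fold. Apoptosis and p53 genes (median 0.17, percentile 94.8, 4 genes) held Bcl2a1b at 1.15-fold, Bax at 1.10-fold and Pmaip1 at 1.37-fold. Cell cycle genes (median 0.15, percentile 92.4, 4 genes) held H2afz at 1.14-fold and Hmgb2 at 1.25-fold. Of the T cell lists, 2 activation genes were measured, Ccl5 (2.16-fold) and Lag3 (0.694-fold), with a median of 0.30, and 1 naive T cell gene, Klf2 (1.62-fold), with a log2 ratio of 0.69. Of cholesterol synthesis, 0 genes reached 50 CPM and 20 UMIs.

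After every microglia-like cell was thinned to 1000 UMIs, P2ry12 was detected in 71.1% of PBS cells (67.7 to 74.3%) and 52.1% of Igfbpl1 cells (49.6 to 54.6%). Tmem119 was detected in 50.9% (47.2 to 54.5%) and 33.5% (31.2 to 35.9%). In B-like cells, which are not known to express either (median depths 2240 and 1640 UMIs), the P2ry12 shares were 2.47% and 3.80% and the Tmem119 shares 2.47% and 5.06%. Igf1r was detected in 7.10% and 7.07% of microglia-like cells, against 0 of 81 B-like cells in the PBS library (up to 3.70%) and 5.06% in the Igfbpl1 library. Il1b was detected in 5.65% (4.12 to 7.54%) and 19.2% (17.3 to 21.3%) of microglia-like cells, against 0 of 81 and 22.8% of B-like cells. Apoe was detected in 31.1% and 59.1%, against 18.5% and 59.5%. The B-like cluster of the Igfbpl1 library also carried the myeloid transcripts Lyz2 and Cxcl2, so it is not a clean background for Il1b and Apoe.

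The third comparison covers the monocyte/macrophage-like class (78 and 430 cells, median depths 4105.5 and 3575 UMIs). Pf4 and Mrc1 were lower in the Igfbpl1 library, and Ccl5 and Ly6a higher. Pf4 and the mannose receptor gene Mrc1, both markers of resident macrophages, stood at 1887 and 36.3 CPM (0.0193-fold, 0.0147 to 0.0248) and at 785 and 40.2 CPM (0.0512-fold, 0.0390 to 0.0665). Ccl5, a chemokine for T cells, was at 31.7 and 1899 CPM (59.8-fold, 33.4 to 120.0). Ly6a rested on 1 PBS UMI and stood at 2.89 and 576 CPM (199.6-fold, 35.7 to 7892), and Il1rn, the interleukin-1 receptor antagonist, also on 1 PBS UMI, at 2.89 and 199.9 CPM (69.3-fold, 12.4 to 2744). The B cell gene Bank1 was at 231 and 6.06 CPM (0.0262-fold, 0.0126 to 0.0495). The scavenger receptor gene Cd163 was listed only in the PBS library, at 129.8 CPM. Ifitm1 (244 CPM), S100a8 (129.9 CPM) and S100a9 (67.2 CPM) were listed only in the Igfbpl1 library.

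Of 19 interferon response genes measured in this class, 12 were higher and 1 lower (median 0.87, percentile 100), and of 30 oxidative phosphorylation genes 20 were higher (median 0.71, percentile 100). Of 16 homeostatic microglia genes, 10 were lower and 1 higher (median -1.13, percentile 0), and of 9 complement genes 6 were lower (median -1.04, percentile 0.0600). All 3 cholesterol synthesis genes measured were lower (median -2.24). At a clustering resolution of 1.5 the class parted into a cluster named microglia with macrophage markers, which held 83.3% of the PBS cells (65 of 78) and 41.9% of the Igfbpl1 cells (180 of 430), a monocyte cluster (16.7% and 48.4%) and a T cell cluster (0 and 30 cells). The class therefore compares different mixes of cells, and Scrublet called 5.81% of its Igfbpl1 cells doublets.

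The fourth comparison covers T-like cells (32 and 301 cells, median depths 3723.5 and 2209 UMIs). Genes of T cell activation and cytotoxicity were higher in the Igfbpl1 library and genes of naive T cells lower. All 9 activation genes measured were higher by at least 1.5-fold (median 1.68, percentile 100), and 7 of 8 naive and central memory genes were lower (median -1.40, percentile 0). Lef1, a transcription factor of naive T cells, stood at 839 and 149 CPM (0.177-fold, 0.135 to 0.233), Cmah at 314 and 55.4 CPM (0.177-fold, 0.113 to 0.279) and Dgka, which damps T cell receptor signals, at 263 and 53.1 CPM (0.202-fold, 0.125 to 0.330). Rgs1, a regulator of chemokine receptors, rested on 3 PBS UMIs and stood at 25.4 and 845 CPM (33.2-fold, 11.3 to 161). Tmem176a had 0 UMIs in the PBS library and stood at 203 CPM in the Igfbpl1 library, and Myo1e at 0 and 172 CPM. Il17a (424 CPM), Trdc (416 CPM), Trdv4 (259 CPM) and the granzyme gene Gzmb (172 CPM) were listed only in the Igfbpl1 library. Of 10 interferon response genes 9 were higher, and the heat shock list had a median of 1.23. Apoe (144 and 1631 CPM) and H2-Ab1 (0 and 82.0 CPM) were higher as well. The median was 0.95 for disease-associated and 0.068 for homeostatic microglia genes. RNA of other cells may therefore be part of these ratios, which was not tested in this class. Cluster 18 is part of this class and had cells in the Igfbpl1 library alone.

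The fifth comparison covers B-like cells (81 and 79 cells) and bipolar cell-like neurons. In B-like cells Lyz2, the lysozyme gene of myeloid cells, rested on 3 PBS UMIs and stood at 14.96 and 3194 CPM (214-fold, 72.8 to 1038), Il1b at 0 and 1074 CPM, and the neutrophil-attracting chemokine gene Cxcl2 at 0 and 699 CPM. Cldn5, a gene of the endothelial tight junction, was listed only in the Igfbpl1 library, at 226 CPM. Itsn2 was at 324 and 91.5 CPM (0.282-fold, 0.160 to 0.477). The cluster held transcripts of other cell types in the Igfbpl1 library. Bipolar cell-like neurons (26 and 112 cells) carried immune transcripts there as well, with Cd74 at 0 and 363 CPM and the galectin gene Lgals3 at 0 and 273 CPM. The photoreceptor channel gene Cngb3 was at 0 and 247 CPM. Lower in these neurons were the neuregulin receptor gene Erbb4, at 540 and 76.2 CPM (0.141-fold, 0.0769 to 0.246), Galntl6, at 511 and 134 CPM (0.263-fold, 0.162 to 0.419), and Ptprm, at 309 and 89.7 CPM (0.291-fold, 0.157 to 0.524).

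The last comparison takes all cells of each library together, where Xcl1 and Klrd1 were higher in the Igfbpl1 library and Pdc lower. The NK cell genes Xcl1, at 5.27 and 194 CPM (36.9-fold, 23.8 to 60.5), and Klrd1, at 14.2 and 293 CPM (20.6-fold, 15.7 to 27.5), had the largest ratios, followed by Ly6a, at 16.6 and 319 CPM (19.2-fold, 14.96 to 25.05). The rod gene Pdc, at 145 and 8.14 CPM (0.0559-fold), was lower, as was Pf4, at 173 and 8.24 CPM (0.0475-fold). All 20 homeostatic microglia genes were lower by at least 1.5-fold (median -1.28), and all 7 MHC class II genes measured were higher (median 1.53). Ratios over all cells also follow the mix of cells, as microglia-like cells made up 72.1% and 47.1%. Within microglia-like cells 8 of 20 homeostatic genes were lower (median -0.50) and 2 of 4 MHC class II genes higher (median 0.85). For Apoe the ratio was 0.984 over all cells, against 1.98 in microglia-like cells and 0.391 in monocyte/macrophage-like cells.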

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

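Chosen only after the result was seen were the split of cells by Xist and Y-linked UMIs, the use of the larger difference within its sets to weigh a sex mix, the tests of the macrophage-type genes and of both their subsets against free RNA, and the test of a part of the pooled mice. In all, 15 tests of an explanation were run, of which 6 argued against it and 9 left it open. The test of a sex mix for the share of other immune cells is among the 6 only under the later rule. Among the 9 left open, those of a mislabelled library and of a response of female mice could not decide here. The tests of both subsets of macrophage-type genes were void, as the subsets were formed from the ratios tested.

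The share of immune cells other than microglia differed between the libraries in opposite directions in both sets of sexed cells. Igfbpl1 minus PBS, the difference was 41.4 points among Xist-only cells and -8.19 points among Y-only cells. B-like cells are part of the latter, at 7.96% of Y-only cells in the PBS and 2.5% in the Igfbpl1 library. Their share was smaller among Xist-only cells too. Among Y-only cells, monocyte/macrophage-like, T-like and plasmacytoid dendritic-like shares were smaller, and NK-like and dendritic-like shares larger. The intervals overlapped for each of these. The difference between the 41.4 and the -8.19 points was not tested.

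The first pattern is the larger share of immune cells other than microglia in the Igfbpl1 library. Shallow barcodes are argued against as the whole cause, since the difference was 37.6 points among cells of 2000 UMIs or more. Its size depends on depth, as that limit left out more microglia-like than other immune cells of the Igfbpl1 library. A different sex mix of the pools is argued against as the whole cause, since it allows no difference among cells of one sex and the larger of the differences within the sets of cells was 41.4 points. The rule written first asked for a large positive difference in both sets. The -8.19 points among Y-only cells did not meet that rule, so by it a sex mix stayed open. In the Igfbpl1 library the percentage of Y-only cells was 37.7 points higher in microglia-like than in other immune cells, so the additional cells may come from a part of the pooled mice, which no label allows to be tested. An effect of Igfbpl1 itself is among the open explanations, untested with 1 library per group.

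The second pattern is the lower homeostatic list in microglia-like cells. A different sex mix is argued against as the whole cause, since the median nearest 0 of the Xist-only and Y-only cells was -0.43. Loss of RNA from long genes is argued against as well, with percentile 0 among lists matched on expression and genomic span, although span went with the ratio across genes. Weighting the cells of both libraries by heat shock content lowered the heat shock median from 1.11 to 0.44, so content was not fully matched, and left the homeostatic median at -0.46, which argues against the part removed as the whole cause. An effect of the treatment stays untested, as does any other difference between the pools, since each group had 1 library.

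The third pattern is the group of macrophage-type genes that were higher in microglia-like cells, which RNA released by other cells of the library could also bring. If it did, neurons would carry the excess too: over Apoc1, Il1b, Wfdc17, H2-Ab1, Cd74 and Fabp5, the median ratio of the excess in bipolar-like and amacrine-like neurons to that in microglia-like cells was 0.59, which leaves free RNA open. It was 1.17 for Cd74, H2-Ab1 and Fabp5 and 0.16 for Apoc1, Il1b and Wfdc17, but both groups were formed from the ratios themselves, so free RNA stays open for each of them. For Ccl2, Hmox1, Ifi27l2a and Pim1 it was 0.10, which argues against free RNA as the whole source of these genes. No biological explanation was tested for them beyond the group itself.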

How the results depend on the processing

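Chosen only after the result was seen were the alternatives restricted to Xist-only and to Y-only cells; the others were chosen beforehand. No paired analysis was possible because each group had 1 library and no result comes from a test. Of 708 values under an alternative, 8 reversed a called direction, all among Y-only cells. Results without a called direction changed sign in 19 values, such as Tnf among Xist-only cells (log2 ratio 0.24), the cell cycle (-0.15) and T cell activation (-0.061) medians among Y-only cells, and Igf1 in the largest single cluster (-0.17). The 22 named genes of 1.5-fold or more kept their direction in 263 of 264 alternative values (all but Apoe among Y-only cells) and their 1.5-fold size in 254. Most of these genes were chosen by the size of their ratio in the same data, so a kept direction says little. The 264 values include the minimum of 500 genes, which repeats the main values. Resolutions of 0.4 and 1.5 were tried on the 9 share differences alone and kept each within its counting interval. Leaving out Scrublet doublets and a mitochondrial limit of 10% (13 cells) did so for every difference and ratio tried. No expression ratio was recomputed at another resolution. At 1.5, 65 PBS and 180 Igfbpl1 monocyte/macrophage-like cells moved to a cluster named microglia, so the microglia-like ratios there are not known. The shares behind the differences moved further: at 1.5, microglia-like cells made up 79.1% and 53.7% (PBS and Igfbpl1), other immune cells 12.5% and 40.1% and monocyte/macrophage-like cells 1.23% and 6.28%, all outside their intervals. The Igfbpl1 share of the last class was 11.1% with the mitochondrial limit, 10.4% with each library clustered on its own and 23.1% after thinning to 1000 UMIs. With that thinning the Igfbpl1 share named dendritic-like fell from 13.2% to 3.06%. A minimum of 500 genes and no mitochondrial limit removed 0 cells, so they test nothing. With each library clustered on its own, 1 of 9 share differences left its interval, as did 31 of 56 values under median-ratio scaling, 31 of 33 in the largest single cluster, 19 of 33 with 50 CPM added and 14 of 42 after thinning to 1000 UMIs, with no called direction reversed. Depth limits genes under about 50 CPM and the smaller classes.

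Among Y-only cells the share differences that reversed were 2.73 points for microglia-like, -8.19 for other immune, -2.63 for monocyte/macrophage-like, -1.63 for T-like, -0.0255 for plasmacytoid dendritic-like and 5.46 for non-immune cells. That of plasmacytoid dendritic-like cells rests on 1 of 490 and 1 of 560 cells. Its intervals overlapped, as did those of the microglia-like, monocyte/macrophage-like and T-like shares. The MHC class I median reversed to -0.016 and the log2 ratio of Apoe, whose PBS UMIs were clumped, to -0.42. List medians there were -0.43 (homeostatic), 0.17 (disease-associated), 0.35 (inflammatory), 0.20 (interferon), 0.67 (MHC class II), 0.34 (immediate early) and 1.02 (heat shock). Among Xist-only cells, shares differed by -39.3 points (microglia-like) and 41.4 points (other immune), and medians were -0.73, 0.70, 1.08, 1.57, 0.98 and 1.23 for homeostatic, disease-associated, inflammatory, interferon, immediate early and heat shock genes. The cause was not tested.

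Median-ratio scaling, which shifts every gene and lets further genes reach 50 CPM, gave medians of -0.38 (homeostatic), 0.44 (disease-associated), 0.67 (inflammatory), 1.04 (interferon), 0.97 (MHC class II), 0.62 (immediate early) and 1.23 (heat shock). Equal weight per cell gave -0.44 for the homeostatic list, and 1 CPM added gave 1.06 for the interferon list. A minimum of 10 CPM, which admits more genes, gave 1.66 for MHC class II. A minimum of 100 CPM, which admits fewer, gave 0.24 for disease-associated and 0.63 for inflammatory genes. With only immune cells in the denominator, the difference for microglia-like cells was -28.8 points. For equal weight and the added CPM the cause was not tested.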

Other observations

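Chosen only after the result was seen were the tests of dilution by free RNA and of a response of female mice, and the values that belong to no test.

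Markers of further cell types are given as sums over all cells of each library. A marker not listed for a library counts as 0 there, so a sum can compare unlike sets of genes. Rod markers, the genes of the photoreceptor cascade, stood at 1514 CPM in the PBS library (1475 to 1553) and 141 in the Igfbpl1 library (134 to 149), and cone markers at 342 and 75.4. Mast cell markers, chiefly proteases of their granules, stood at 1.05 and 41.5 CPM. Endothelial markers, of which Cldn5 was listed only in the Igfbpl1 library, stood at 73.8 and 124. Horizontal cell markers had 0 UMIs in the PBS library, which can mean that they were not listed, and stood at 16.8 in the Igfbpl1 library. Plasma cell markers stood at 40.6 and 18.1 and mural cell markers at 28.2 and 10.5. The intervals overlapped for retinal ganglion cell markers (75.6 and 81.7), pigment epithelium or melanocyte markers (2.90 and 1.90) and fibroblast markers (0 and 0.317).

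T-like cells of the Igfbpl1 library also carried more cell cycle transcripts (4 of 5 genes measured higher by at least 1.5-fold, median 1.10) and glycolysis transcripts (7 of 11, median 0.86). Of 81 cytosolic ribosome genes, 29 were lower, 1 higher and 51 within 1.5-fold. Their median was -0.42 (percentile 0.485), but random lists of like expression were also below 0, at -0.27 (-0.39 to -0.094). Monocyte/macrophage-like cells of the Igfbpl1 library had higher glycolysis genes (6 of 11, median 0.93) and MHC class I genes (6 of 11, median 0.83), with Spp1 at 60.6 and 384 CPM and Il1b at 989.7 and 2083 CPM. Il1b did not stand for its list: of 21 inflammatory genes in this class, 2 were higher and 7 lower (median -0.32, percentile 4.90). Of 21 immediate early genes, 2 were higher and 9 lower (median -0.47, percentile 0.975).

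A handling difference shared by the whole Igfbpl1 library was weighed for the higher heat shock list, and 1 of 4 other classes had a median above the level set for it: it was 1.23 in T-like, 0.49 in B-like, 0.30 in monocyte/macrophage-like and 0.079 in bipolar-like cells, so the test left it open.

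Further tests bear on the patterns weighed above. Dilution of microglial RNA by free RNA stays open: the median of 29 complement and lysosome genes lay 0.50 above the homeostatic one on the log2 scale, but free RNA could bring both kinds of gene in amounts that are not known. In B-like and bipolar-like cells of the Igfbpl1 library the medians were higher for complement (2.45 and 1.80), lysosome (1.47 and 1.25) and homeostatic genes (0.93 and 1.15) alike. A mislabelled library could be neither shown nor excluded, as 0 of the libraries listed the Igfbpl1 transcript. Blood left in the tissue stays open for the larger share of other immune cells. The Igfbpl1 library held 27 UMIs of erythrocyte markers and the PBS library 0, where a marker not listed also counts as 0. Neutrophil markers stood at 151.6 and 179.7 CPM (Igfbpl1 and PBS), with S100a8 and S100a9 listed only in the Igfbpl1 library. A response of female mice as a group (59.4% of Xist-only Igfbpl1 cells were other immune cells) stays open, since no label names the mouse a cell came from.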
